A study of Pimephales promelas with 31 samples.

How the data were processed

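Female fathead minnows (Pimephales promelas, a small freshwater fish used in toxicity testing) were left unexposed as controls or kept for 96 h in 4 µg/L silver nitrate (AgNO3, a source of silver ions) or in 70 µg/L silver nanoparticles coated with polyvinylpyrrolidone (PVP-AgNP). RNA of brain and of liver was labelled with Cy3 and hybridised to 1-colour Agilent oligonucleotide arrays, 1 array per sample. The 31 arrays were grouped from the labels: brain control (6), brain AgNO3 (5), brain PVP-AgNP (5), liver control (6), liver AgNO3 (5) and liver PVP-AgNP (4, numbered 1, 2, 3 and 5). Per the labels, fish were exposed in triplicate with several females in each, but which exposure replicate or how many fish an array stands for is not given in the sources used here, so every p-value measures the spread between these arrays.

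The authors' scanner files hold intensities: per the file headers, Agilent Feature Extraction ran with its background correction off and its spatial and multiplicative detrending on, and wrote a processed intensity for each spot. Checked on the values to a relative tolerance of 0.01, a fitted spatial surface was what was subtracted from at least 99.68% of the spots of each array, and the local background was not. Division by a multiplicative surface was found on 18 arrays and not on the other 13, which lie in every group. Between 2.11% and 42.5% of an array's spots carried a surrogate value in place of a signal too dim to measure, most of all on brain control 5. Levels varied between arrays, and no step between arrays is recorded in the headers. Each array had 62372 spots, of which 61053 were not controls. They carried 49849 probe names of 60 bases, with 44586 distinct sequences, and 10394 probe names shared their sequence with another name. The names (8524 beginning CONTIG, 26117 SINGLET and 15208 UF_Ppr) are assembly identifiers. The files pair them with no gene, and 0 of the 49849 were found among the symbols, synonyms, locus tags and accessions of the 64593 genes in the reference table, so probes are reported by identifier and sequence. The gene lists fixed before the data were examined could therefore not be tested.

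The deposited series matrix holds log2 values of the same arrays on another scale. Its column medians ran from -0.02 to 0.04 in brain and from -0.07 to 0.05 in liver. Each probe's median over the arrays of a tissue was 0 to within 1e-06, so the values are centred per probe and tissue. Differences between arrays correlated with those of quantile-normalized log2 intensities (r across probes, median 0.99 in each tissue), with slopes of 0.98 in brain and 1.02 in liver, which fixes scale and direction. The method of normalization and each probe's absolute level stay unknown, and these values served as an alternative only.

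Control spots and spots with an outlier mark were left out, spots of 1 probe were averaged, and log2 of the processed intensity was taken relative to each array's 75th percentile. Probes were kept in a tissue when well above background on at least as many arrays as its smallest group holds (5 in brain, 4 in liver). This left 44354 probes in brain, 39511 in liver and 37797 in both. No spot outside the controls was saturated. Where no array of a group had a probe well above background, the fold is a bound: the bright group's mean against the dim group's mean of, per array, the higher of the dimmest probe well above background and the probe's own value.

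Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with all 3 groups of a tissue in 1 fit, and a probe was called at a Benjamini-Hochberg adjusted p under 0.05. Differences between tissues were interaction contrasts in a fit of all 31 arrays. Scores of single arrays were compared by exact two-sided permutation tests. These were 44 tests, and their p-values were adjusted together by the Benjamini-Hochberg method. Tables were read with the data.table package (version 1.17.8) and figures drawn with matplotlib 3.10.9 in Python 3.11.15. The main design, the alternatives and the rule for named probes were chosen before the data were examined, with exceptions given where they occur. The written plan counts 15 brain arrays in some entries. There are 16, and all were used.

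The rule named up to 12 genes each way per comparison, those with the largest log2 changes among calls in which every exposed array lay on the same side of the control mean. With identifiers in place of gene names it was narrowed, after the data were examined, to 2 probes of distinct sequence each way. The part of the rule that always reports particular genes could not be applied.

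The arrays lay on 4 slides. Slide 1 held liver AgNO3 replicates 1 and 2, liver control 1, 2 and 3 and liver PVP-AgNP 1, 2 and 3. Slide 2 held liver AgNO3 3, 4 and 5, liver control 4 and 5, liver PVP-AgNP 5 and brain control 1. Slide 3 held brain AgNO3 1 and 2, brain control 2, 3 and 4 and brain PVP-AgNP 1, 2 and 3. Slide 4 held brain AgNO3 3, 4 and 5, brain control 5 and 6, brain PVP-AgNP 4 and 5 and liver control 6. Slide was tested as a term of the model and comparisons were repeated within slides. Liver control 6 is the only liver array on slide 4, and brain control 1 the only brain array on slide 2. In a fit of 1 tissue the slide term therefore takes up that control and in effect leaves it out. Each slide had 1 scan time and all were scanned on 1 day, so scan time cannot be told apart from slide.

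Alternatives chosen beforehand were normexp background correction of the mean signal with the local background (offset 50, spots with an outlier mark included, no detrended or surrogate values), quantile normalization, median centring, no filter or a stricter filter on dim probes, outlier spots kept, the series matrix values, slide or replicate number as a block, only the 2 groups compared, array weights, and each array left out in turn. Chosen after the data were examined were leaving out the 3 brain arrays with raised negative-control spots (median processed intensity above 10), 1 probe name per sequence, leave-one-out for the differences between tissues, the calls shared by tissues, the scores of single arrays and the tissue-enriched probe sets. A probe was tissue-enriched when its mean differed at least 16-fold between liver and brain arrays of the exposure not under comparison. Sets drawn from control arrays were also looked at before these were settled on.

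The scripts were tested on simulated data made from these arrays with 200 probes changed. In brain, 17.4% of probes changed by a log2 of 1 and 60.2% of those changed by 2 were recovered for AgNO3, and 15.8% and 57.6% for PVP-AgNP. In liver, 1.85% and 31.5% were recovered for AgNO3, and 0% and 22.3% for PVP-AgNP. For the differences between tissues, 0.99% and 24.2% were recovered for AgNO3, and 0% and 25.5% for PVP-AgNP. The number of arrays limits the precision, and liver arrays varied more than brain arrays.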

Results

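Gene expression was measured in brain and liver of female fathead minnows after 96 h in 4 µg/L AgNO3 or 70 µg/L PVP-AgNP, and in controls. The study asked what ionic silver and coated silver nanoparticles do to transcription, so each exposure was compared with its controls, the exposures with each other, and the tissues with each other. The doses differ, so a difference between AgNO3 and PVP-AgNP is one between these treatments and not between forms of silver at 1 dose. The array's 75th percentile of intensity lay between 120 and 870. The share of probes well above background was 52.7% to 80.4% on liver arrays and 77.0% to 90.3% on 13 of the brain arrays. It was 34.9% on brain control 5, 40.6% on brain PVP-AgNP 4 and 51.4% on brain PVP-AgNP 5, and these 3 arrays also had raised negative-control spots. Arrays of 1 group correlated with r between 0.840 and 0.972 across probes, and arrays of different tissues at 0.760 or less. Changes are log2 differences of group means, relative to each array's 75th percentile, with their standard error (SE).

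**Figure D1:**
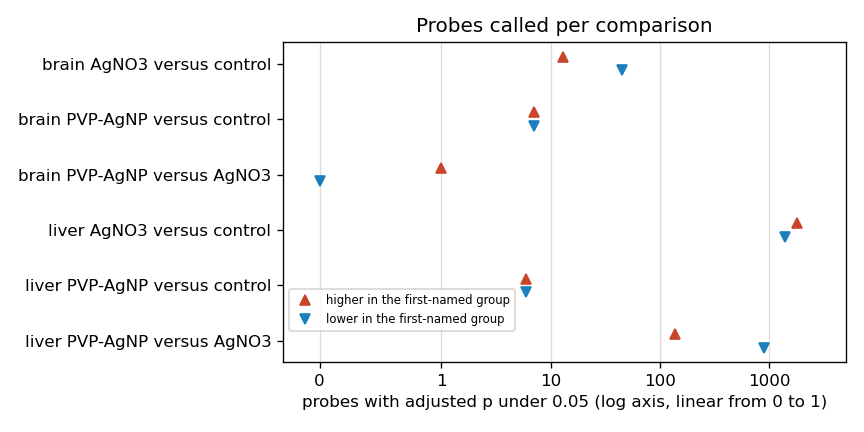
Probes called in each comparison (limma, adjusted p under 0.05). The x axis is the number of probes, on a log scale above 1, and each line shows the probes higher (upward triangle) and lower (downward triangle) in the group named first. Liver AgNO3 stands out with 1781 higher and 1385 lower, against 6 and 6 for liver PVP-AgNP. With only the 2 groups compared, 2965 probes were called for AgNO3 in liver and 2626 in brain.

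In brain, AgNO3 changed 58 of 44354 probes, 13 upward and 45 downward, and 57 of these by at least 2-fold. Probe UF_Ppr_AF_118252 (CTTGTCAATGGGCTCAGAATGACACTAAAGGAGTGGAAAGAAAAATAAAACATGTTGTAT) rose from 0.32 ± 0.27 (SD, n = 6) in controls to 2.42 ± 0.15 (n = 5), a log2 change of 2.095 (SE 0.19, limma adjusted p = 6.14e-05). Probe SINGLET_3170 (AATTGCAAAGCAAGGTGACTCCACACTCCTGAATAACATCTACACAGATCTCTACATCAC) rose by 1.83 (SE 0.31, limma adjusted p = 0.0301). Probe SINGLET_7988 (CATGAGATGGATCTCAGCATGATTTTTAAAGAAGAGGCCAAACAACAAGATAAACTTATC) fell from -2.24 ± 0.39 to -5.94 ± 0.14, at least 12.98-fold, and was not well above background on any of the 5 AgNO3 arrays (limma adjusted p = 6.01e-06). The bound holds for the processed intensities, and with normexp the fitted log2 change was -1.36 (limma adjusted p = 0.0487). Probe SINGLET_894 (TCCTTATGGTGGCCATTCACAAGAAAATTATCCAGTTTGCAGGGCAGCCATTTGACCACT) had a log2 change of -3.20 (SE 0.36, limma adjusted p = 7.91e-04) and was well above background on 2 of 5 AgNO3 arrays. The call of SINGLET_3170 was lost with slide as a term, with the replicate number as a block, without the 3 arrays with raised negative-control spots and without AgNO3 1, 3, 4 or 5 or any 1 control, and that of SINGLET_894 with normexp.

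The count depended on the arrays, the scaling and the model. With only the 2 groups compared 2626 probes were called (1383 higher and 1243 lower), with array weights 3336 (1523 and 1813) and with the replicate number as a block 7 (2 and 5). With slide as a term, which in effect leaves out control 1, 23 probes were called, 22 of them among the 58. Leaving out control 1 alone gave 22, so the fall cannot be put down to slide. Within slides 1 was called on slide 3 and 0 on slide 4, where 4835 had an unadjusted p under 0.05 in limma. Quantile normalization called 48 higher and 77 lower, and the series matrix values 49 and 80. The count was 33 without AgNO3 2, 23 without AgNO3 3, 23 without AgNO3 4 and 29 without AgNO3 5. It was 22, 27, 32, 30, 32 and 27 without control 1, 2, 3, 4, 5 and 6, and 319, 167 and 99 without PVP-AgNP 1, 2 and 3, which share the estimate of the spread. Without the 3 arrays with raised negative-control spots 41 probes were called.

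PVP-AgNP changed 14 probes in brain, 7 upward and 7 downward. Probe CONTIG1413 (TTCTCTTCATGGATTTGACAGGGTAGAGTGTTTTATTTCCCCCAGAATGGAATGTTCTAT) rose from 0.29 ± 0.33 (SD, n = 6) to 2.304 ± 0.40 (n = 5), by a log2 of 2.02 (SE 0.26, limma adjusted p = 0.00868). Probe SINGLET_48040 (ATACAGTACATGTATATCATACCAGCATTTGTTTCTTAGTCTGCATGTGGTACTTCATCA) rose by 1.97 (SE 0.23, limma adjusted p = 0.00424). Probe SINGLET_7988, which AgNO3 also lowered, had a log2 change of -1.92 (SE 0.25, limma adjusted p = 0.00868) and was well above background on 3 of 5 PVP-AgNP arrays. Probe SINGLET_6767 (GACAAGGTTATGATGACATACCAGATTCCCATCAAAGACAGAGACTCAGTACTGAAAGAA) had a log2 change of -1.89 (SE 0.31, limma adjusted p = 0.0443). All 4 calls were lost with only the 2 groups compared and with the replicate number as a block, where limma called 0 probes (4056 and 3977 at an unadjusted p under 0.05). The calls of both lower probes were lost with normexp, quantile normalization, median centring and the series matrix values, and these and that of CONTIG1413 without the 3 arrays with raised negative-control spots. That of SINGLET_6767 was also lost with no filter and without any 1 brain array other than PVP-AgNP 1 or 2.

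The median of all probes was -0.13 in this comparison and 0.00 after quantile normalization, which called 6 higher and 3 lower. Normexp called 5 and 1, median centring 6 and 1, and the series matrix values 6 and 2. The stricter filter on dim probes called 24 and array weights 165 (33 higher and 132 lower). With slide as a term 8 were called (6 higher and 2 lower), all among the 14. Within slides limma called 0 on slide 3 and 0 on slide 4, with 2456 and 5337 at an unadjusted p under 0.05. The count was 6 without AgNO3 1, 22 without AgNO3 3 and 6 without AgNO3 4. It was 6, 6, 8 and 6 without control 1, 2, 3 and 6, and 189, 45 and 7 without PVP-AgNP 1, 2 and 3. Without the 3 arrays with raised negative-control spots 20 were called, of which 5 were among the 14.

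Between the exposures, 1 brain probe differed. UF_Ppr_AF_103842 (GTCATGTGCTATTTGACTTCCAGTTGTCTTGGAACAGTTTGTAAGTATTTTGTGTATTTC) was at 4.85 ± 0.17 (SD, n = 5) under PVP-AgNP and 3.32 ± 0.34 (n = 5) under AgNO3, a difference of 1.53 (SE 0.18, limma adjusted p = 0.0164). Against controls its log2 change was -1.59 under AgNO3 and -0.06 under PVP-AgNP. The call was lost with normexp (1710 probes at an unadjusted p under 0.05 in limma), median centring (5166), slide as a term (3847), the replicate number as a block (4172) and only the 2 groups compared (3504), and without AgNO3 2, 4 or 5 or PVP-AgNP 1, 3 or 4, each of which left 0 calls (between 2745 and 6124). Within slides limma called 1 probe on slide 3 and 0 on slide 4, where 3301 had an unadjusted p under 0.05. Array weights gave 2 calls. Without PVP-AgNP 2 there were 487 calls, 31 higher and 456 lower, without PVP-AgNP 5 there were 4, and without the 3 arrays with raised negative-control spots 23. The median of all probes moved from -0.11 to 0.13 with median centring.

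In liver, AgNO3 changed 3166 of 39511 probes, 1781 upward and 1385 downward, with a median size of 2.03 (log2) and 904 changed at least 8-fold. Probe SINGLET_45559 (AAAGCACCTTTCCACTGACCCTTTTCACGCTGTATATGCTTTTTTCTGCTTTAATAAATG) rose from -3.26 ± 2.45 (SD, n = 6) to 5.16 ± 1.77 (n = 5), by a log2 of 8.41 (SE 1.26, limma adjusted p = 6.06e-04), and was well above background on 3 of 6 control arrays. Probe SINGLET_302 (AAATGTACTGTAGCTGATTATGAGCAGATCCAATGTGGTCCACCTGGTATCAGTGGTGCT) rose by 8.31 (SE 1.31, limma adjusted p = 8.98e-04), with 4 of 6 control arrays well above background. Probe SINGLET_46260 (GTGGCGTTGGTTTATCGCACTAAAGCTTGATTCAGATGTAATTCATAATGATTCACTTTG) fell from 5.61 ± 2.63 to -2.75 ± 3.41, a log2 change of -8.36 (SE 1.63, limma adjusted p = 0.00462), with 3 of 5 AgNO3 arrays well above background. Probe SINGLET_305 (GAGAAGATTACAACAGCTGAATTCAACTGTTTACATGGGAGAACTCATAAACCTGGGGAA) had a log2 change of -5.59 (SE 1.52, limma adjusted p = 0.0355), and its call was lost with quantile normalization, with the series matrix values, with slide as a term, with the replicate number as a block and without AgNO3 2, 3, 4 or 5 or control 1, 2, 4 or 6. Among 1212 probes at least 16-fold brighter in brain than liver, 143 (11.8%) rose and 4 (0.33%) fell, and among 1584 at least 16-fold brighter in liver, 58 (3.66%) rose and 160 (10.1%) fell, beside 4.51% and 3.51% of all probes. After quantile normalization the liver-enriched counts were 57 (3.631%) and 67 (4.268%) of 1570 and the brain-enriched ones 101 and 3 of 1245. Of all probes, 3.796% rose and 1.982% fell there, so liver-enriched probes still fell more often than all probes. With normexp the counts were 11 and 108 of 959 and 21 and 0 of 532, beside 2.668% and 4.275% of all probes.

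Slide as a term left 1580 calls (1272 higher and 308 lower), 1559 of them among the 3166. That fit in effect also leaves out control 6, and leaving out control 6 alone gave 1890, so the fall is not the effect of slide alone. Within slides 3 were called on slide 1 and 1062 on slide 2. Normexp called 1054 higher and 1689 lower and moved the median of all probes from -0.05 to -0.17, and median centring, which called 1599 and 1326, moved it to -0.19. With the replicate number as a block 1248 were called higher and 257 lower, and with array weights 7665 and 8715, so the balance of higher and lower calls differed between these settings. The count was 3716, 2996, 2077, 1731 and 1757 without AgNO3 1, 2, 3, 4 and 5. It was 2193, 2168, 4419, 1957, 4615 and 1890 without control 1, 2, 3, 4, 5 and 6. AgNO3 1 and controls 3 and 5, without which the count rose, had the lowest median correlations with their groups (0.87, 0.88 and 0.87).

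PVP-AgNP changed 12 liver probes, 6 upward and 6 downward, each at least 4-fold. Probe SINGLET_29776 (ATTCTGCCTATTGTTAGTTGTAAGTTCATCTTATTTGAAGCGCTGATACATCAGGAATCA) rose from -6.22 ± 0.57 (SD, n = 6), not well above background on any control array, to -0.87 ± 0.41 (n = 4), at least 24.5-fold for the processed intensities (limma adjusted p = 6.73e-04). Probe UF_Ppr_AF_109653 (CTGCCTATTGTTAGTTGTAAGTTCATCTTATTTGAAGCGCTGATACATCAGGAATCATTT), which shares 57 bases with it, rose at least 22.9-fold (limma adjusted p = 0.00109). With normexp their fitted log2 changes were 1.69 and 1.56 (limma adjusted p = 0.0285 and 0.0360), under both bounds. Probe UF_Ppr_AF_113208 (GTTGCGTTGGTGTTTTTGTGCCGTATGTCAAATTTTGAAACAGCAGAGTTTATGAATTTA) fell from 9.69 ± 0.16 to 5.96 ± 0.59, a log2 change of -3.73 (SE 0.58, limma adjusted p = 0.0360). Probe SINGLET_45153 (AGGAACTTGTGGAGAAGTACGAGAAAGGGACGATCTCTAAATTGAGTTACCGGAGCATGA) had a log2 change of -3.25 (SE 0.47, limma adjusted p = 0.0228). The call of UF_Ppr_AF_113208 was lost with quantile normalization, with the series matrix values, with the replicate number as a block and without AgNO3 5, control 1, 2, 4 or 6 or any 1 PVP-AgNP array, and that of SINGLET_45153 with the replicate number as a block and without control 1, 2, 4 or 6 or PVP-AgNP 1, 2 or 3.

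Liver PVP-AgNP 5 stood apart from the rest of its group. Over 1200 probes at least 16-fold brighter in brain than in liver, chosen on the AgNO3 arrays, its median level was -1.20, against -4.52, -3.16 and -3.69 on the other PVP-AgNP livers, and 1194 of them were well above background. Across these probes its levels correlated with the brain levels at r = 0.92, against 0.58 or less on every other liver array. Over 2160 probes at least 16-fold brighter in liver, the array medians differed from controls by -0.59 (exact two-sided permutation p = 0.00952, adjusted 0.0381), or by -0.23 without PVP-AgNP 2. After quantile normalization the difference was -0.49 (exact two-sided permutation p = 0.0286, adjusted 0.0833), which did not pass. With normexp it was -0.77 (exact two-sided permutation p = 0.00952, adjusted 0.0381). Of the 2160 probes limma called 0 higher and 5 (0.23%) lower, beside 0.015% of all probes each way. In the limma test of all probes, 47 were called without PVP-AgNP 5, 24 higher and 23 lower. The count was also 34 without AgNO3 1, 6, 7, 85, 5, 114 and 5 without control 1, 2, 3, 4, 5 and 6, and 5 and 7 without PVP-AgNP 1 and 2. With slide as a term 19 were called, 10 of them among the 12. Within slides limma called 1 on slide 1 and 0 on slide 2 (2702 at an unadjusted p under 0.05), but slide 2 holds 1 PVP-AgNP array, this PVP-AgNP 5, which is assumed to vary like the other groups, so it is no check of slide. Normexp called 39 and moved the median of all probes from 0.09 to -0.02, the stricter filter on dim probes called 38, array weights 4381 and the replicate number as a block 2.

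**Figure D2:**
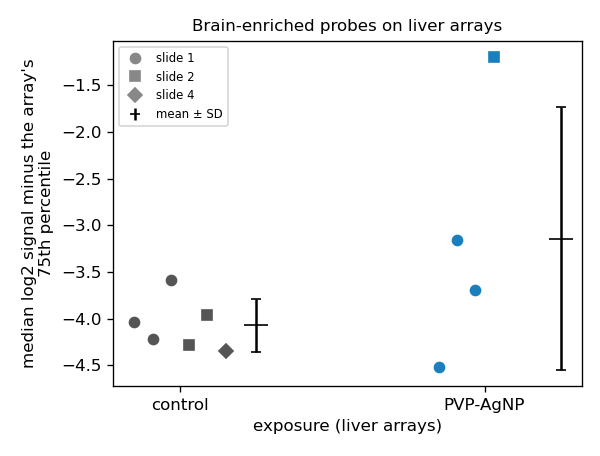
Median level of 1200 brain-enriched probes on each control and PVP-AgNP liver array. The y axis is log2 signal minus the array's 75th percentile, marker shape gives the slide, and the bar is the group mean ± SD. One PVP-AgNP array, replicate 5, lies at -1.20 while the controls lie between -4.34 and -3.58.

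Between the exposures, 1019 liver probes differed, 136 higher and 883 lower under PVP-AgNP than under AgNO3. Probe SINGLET_45559 was at -3.25 ± 2.70 (SD, n = 4) under PVP-AgNP and 5.16 ± 1.77 (n = 5) under AgNO3, a difference of -8.40 (SE 1.40, limma adjusted p = 0.00587), with 3 of 4 PVP-AgNP arrays well above background. Probe UF_Ppr_AF_110866 (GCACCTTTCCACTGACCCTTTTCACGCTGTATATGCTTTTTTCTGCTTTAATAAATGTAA), which shares 57 bases with it, differed by -7.79 (SE 1.28, limma adjusted p = 0.00567), again with 3 of 4. Probe SINGLET_46260 was higher by 7.28 (SE 1.81, limma adjusted p = 0.0454) and UF_Ppr_AF_110304 (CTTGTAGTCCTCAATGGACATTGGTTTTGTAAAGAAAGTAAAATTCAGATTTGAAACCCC) by 5.26 (SE 1.12, limma adjusted p = 0.0192). On the AgNO3 arrays the former was well above background on 3 of 5 and the latter on 1 of 5, and with normexp the difference of the latter was 1.94 (limma adjusted p = 0.0144). Of the 883 probes lower under PVP-AgNP, 834 were called higher under AgNO3 than in controls, and of the 136 higher ones 51 were called lower, in comparisons that share the AgNO3 arrays. Of the 3166 probes called for AgNO3 against controls, 2869 (90.6%) changed in the same direction under PVP-AgNP, against the same control arrays. The call of SINGLET_46260 was lost with normexp, with slide as a term, with only the 2 groups compared and without AgNO3 2, 3, 4 or 5, control 1, 2, 3, 4 or 6 or PVP-AgNP 1, 3 or 5, and that of UF_Ppr_AF_110304 with the replicate number as a block and without AgNO3 3 or 4 or PVP-AgNP 1, 2 or 3. With slide as a term 638 were called, 621 of them among the 1019. Within slides 1 was called on slide 1 and 5 on slide 2, where PVP-AgNP 5 is the 1 PVP-AgNP array and is assumed to vary like the other groups. The count was 577, 493 and 553 without AgNO3 3, 4 and 5, and 394 and 646 without PVP-AgNP 1 and 3, and array weights called 3014.

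Comparisons with the same controls share chance. In brain, 7 probes of 6 distinct sequences were called alike for both exposures, 4 upward and 3 downward, where independent lists would share 0.00205 and 0.0071. Unchanged groups were simulated by drawing whole arrays' deviations from their group means with replacement, controls included, and shared at most 1. The changes of all brain probes correlated at r = 0.47 (covariance 0.137), where the simulations gave a median r of 0.49 (mean covariance 0.109). With the controls split 3 and 3 the covariance was 0.027 and 0.077, and 2 and 0 probes were shared, the 2 upward, where independent lists would share 0.000338. In liver, 9 probes were called alike, 4 upward and 5 downward, where independent lists would share 0.27 and 0.21. The simulations shared a median of 0, a mean of 13.9 and at most 876. The same array's deviations could be drawn into both exposed groups, so the simulations do not show what shared controls alone give. The liver correlation was 0.55 (covariance 0.552), the simulated median 0.42 (mean covariance 0.169), and split controls gave a covariance of 0.279 and 0.239. With the former split 29 upward and 29 downward probes were shared, where independent lists would share 34.9 and 3.31, with 5 called in opposite directions, and with the latter 4 upward and 0 downward, where they would share 0.49 and 0.23. With the replicate number as a block 0 probes were called alike in brain and 2 in liver.

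Tissues responded differently to AgNO3 at 1956 of 37797 probes, 1254 with the higher change in liver and 702 in brain. Of these 1495 were called in liver, 7 in brain and 454 in neither. With slide as a term 1172 differed (921 and 251), 1137 of them among the 1956, quantile normalization called 956 and 301, and normexp, which moved the median of all probes from -0.07 to -0.25, called 906. The replicate number as a block called 856 and 155. For PVP-AgNP 6 probes differed. The change in liver was higher than in brain at UF_Ppr_AF_112610 by 3.11 and at CONTIG10307 by 3.06, and the difference was -2.31 at UF_Ppr_AF_105470 and -3.33 at UF_Ppr_AF_113634 (each with a limma adjusted p of 0.0400 or less, chosen as the largest after the values were seen). Quantile normalization moved the median of all probes from 0.21 to 0.02 and left 1 call, normexp gave 0 higher and 6 lower, and slide as a term 2 and 2. No filter on dim probes left 2 of the 6, and the replicate number as a block left 0 (3763 at an unadjusted p under 0.05 in limma). Without the 3 arrays with raised negative-control spots 2 were called, but 0 of the 6 were among them. The 6 became 66 without liver AgNO3 1, 330 and 358 without liver control 3 and 5, 108, 14 and 283 without liver PVP-AgNP 1, 3 and 5, and 16 and 11 without brain PVP-AgNP 2 and 4. They became 3 without brain control 1 or liver control 1, and 2 without brain control 2, 4, 5 or 6, brain PVP-AgNP 3 or 5 or liver control 2.

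AgNO3 moved some probes alike in both tissues. Of 50 brain calls also tested in liver, 19 (18 distinct sequences) were called in the same direction there, 3 upward and 16 downward, none in the opposite one, where independent lists would share 1.81. Fisher's exact test, one-sided for more sharing, gave p = 0.0150 for the upward and 2.18e-14 for the downward probes, across probes that are not independent replicates. UF_Ppr_AF_118252 rose by 2.095 in brain and 2.76 in liver (SE 0.49, limma adjusted p = 0.00234). SINGLET_7988 was also called lower in liver (limma adjusted p = 1.02e-04), where 0 of 5 AgNO3 arrays were well above background, as in brain. SINGLET_6767 had a log2 change of -3.20 in brain, with 4 of 5 AgNO3 arrays well above background, and of -4.04 in liver (SE 0.39, limma adjusted p = 7.45e-05), with 1 of 5. The shared count was 11 without brain AgNO3 2, 3 or 4 or brain control 1, 2, 4 or 6, and 31 without brain PVP-AgNP 1. With slide as a term it was 9, with normexp 12, with the replicate number as a block 5 and with array weights 1279.

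The 50 brain probes were also scored on each liver array, as the mean of the 13 that rose minus the mean of the 37 that fell. AgNO3 livers scored 3.90 ± 0.59 (SD, n = 5) and control livers 1.66 ± 0.51 (n = 6), a difference of 2.24 (exact two-sided permutation p = 0.00217, the smallest this design allows, 0.0191 adjusted over 44 tests). PVP-AgNP livers scored 3.08 ± 0.40 (n = 4), 1.43 above controls (exact two-sided permutation p = 0.00952, adjusted 0.0381). Control livers 3 and 5 scored 2.15 and 2.45, against 1.21 to 1.499 on the other 4, and their median correlation with their group was 0.88 and 0.87, against 0.92 or more. All 5 AgNO3 and all 4 PVP-AgNP livers lay above every control liver, and with slide as a term the differences were 2.11 and 1.40. With normexp they were 1.497 (adjusted 0.0191) and 0.91 (adjusted 0.0299). In the other direction, liver AgNO3 probes scored 0.43 higher in AgNO3 than control brains (exact two-sided permutation p = 0.0195, adjusted 0.0659), which did not pass. After quantile normalization this difference was 0.49 (adjusted 0.0191). Without brain AgNO3 3, which stood apart on this score, it was 0.26 (exact two-sided permutation p = 0.0476, unadjusted), so this array carried part of it.

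**Figure D3:**
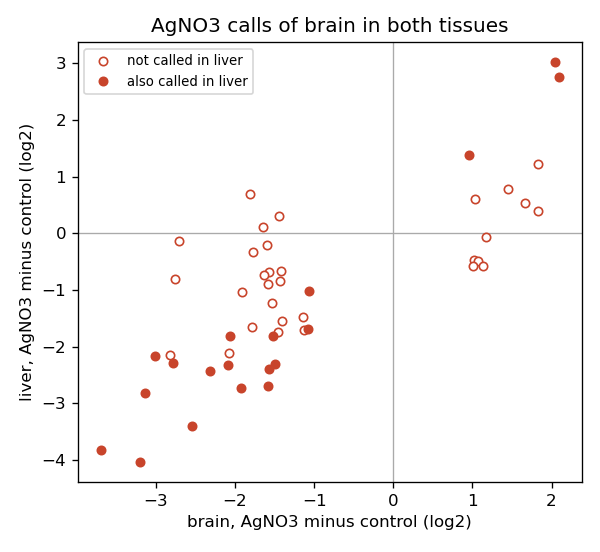
Log2 change under AgNO3 of the 50 probes called in brain, in brain (x axis) and in liver (y axis). Filled points are the 19 probes also called in liver, and 42 of the 50 have the same sign in both tissues.

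**Figure D4:**
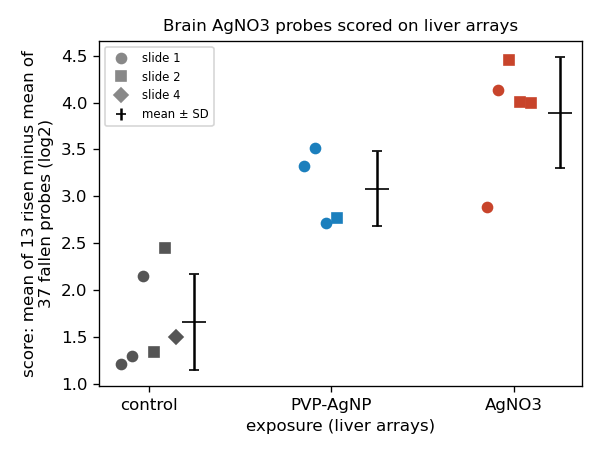
Score of the brain AgNO3 probes on each liver array (y axis, log2), by exposure. Marker shape gives the slide and the bar the group mean ± SD. The AgNO3 arrays lie between 2.88 and 4.45, the PVP-AgNP arrays between 2.72 and 3.52 and the controls between 1.21 and 2.45.

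Control liver and control brain differed at 19818 of 37797 probes, 9124 brighter in liver and 10694 in brain, as a check that the tissue labels hold. Quantile normalization called 10528 and 9499 and moved the median of all probes from -0.11 to 0.14.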

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

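The tests of tissue-enriched probes, array scaling, slide, dilution and handling and the reading of the random regroupings were chosen after the results were seen. The regrouping of same-numbered arrays, and the tests of mixed-in brain RNA, a swapped label and carry-over, were written down before their results were.

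In 82 groups of arrays tested for a value far from the others, 7 were found (8.54%), where chance gives about 1 in 20. Brain control 5 had 34.9% of probes well above background, against 84.5% to 90.3% on the other brain controls, and a log2 negative-control median of 5.66, against 1.02 to 2.42. Brain AgNO3 3 had a 75th percentile of 8.23 (log2 intensity), against 9.05 to 9.36 on the rest of its group. Its score of the liver AgNO3 probes was -0.93, against -1.89 to -1.62. Liver PVP-AgNP 2 had a median of 0.030 over 2160 liver-enriched probes, against 1.41 to 1.61. Probe SINGLET_302 lay at 2.48 on liver AgNO3 2, against 5.85 to 6.99 on the other AgNO3 livers. Probe SINGLET_46260 lay at 0.32 on liver control 5, against 5.90 to 6.96 on the other control livers. The difference between tissues itself passed limma's test at 1956 probes for AgNO3 and at 6 for PVP-AgNP.

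Liver-enriched probes lay lower on AgNO3 livers (difference of array medians -0.33, exact two-sided permutation p = 0.0411, adjusted 0.101, which did not pass, and -0.19 without AgNO3 5), and brain-enriched probes higher (1.02, p = 0.00433, adjusted 0.0299). Slide as a term left 0.98 of the latter, which argues against slide as its whole cause. A narrower range of intensities on the AgNO3 arrays may account for part of this. Their log2 range from the 5th to the 95th percentile was 9.42, against 10.6 on controls (exact two-sided permutation p = 0.0238, adjusted 0.0748, which did not pass). Quantile normalization turned the liver-enriched difference into 0.043 and left 0.65 of the brain-enriched one, while normexp gave -0.63 and 0.15. After quantile normalization the median fitted change of the liver-enriched probes was still -0.27, beside -0.09 for all probes, so the scalings do not decide it. Dilution of liver RNA by RNA of other cells stays open too, with 3.66% of liver-enriched probes called higher beside 4.51% of all probes. A change of liver transcription under AgNO3 is among the open explanations and cannot be told apart from these.

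The 19 AgNO3 probes called alike in brain and liver were set against 4 explanations. Liver RNA or signal on brain arrays, or brain RNA or signal on liver arrays, was not among them and was not tested. Brain RNA on liver arrays stays open, with UF_Ppr_AF_105526 at 0.16 in control brains and -4.09 in control livers. Liver RNA on brain arrays stays open too. SINGLET_8133 was at 2.61 in control livers and -1.09 in control brains, and SINGLET_31835 at 0.53 and -2.80. The contrast was largest for 4 of the 19, SINGLET_6697, SINGLET_7631, SINGLET_790 and SINGLET_9313. These were at least 16-fold brighter in control livers than in control brains. SINGLET_7631 and SINGLET_9313 also share a stretch of sequence, so the 18 distinct sequences need not be 18 separate targets. The score of brain probes on livers kept a difference of 2.34 after quantile normalization and 2.11 with slide as a term, which argues against scaling and slide as the whole cause. With normexp it fell from 2.24 to 1.497 (exact two-sided permutation p = 0.00217, the smallest this design allows), so its size depends on that setting. Only 1 of 100 regroupings that moved same-numbered brain and liver arrays together, the real one, shared as many calls (highest other 1). The other regroupings called at most 8 brain probes, so none could share 19, and the labels do not say that equal numbers mark 1 fish. The regroupings therefore cannot decide on inherited differences between fish. Deviations of same-numbered brain and liver arrays correlated at r over 0.1 in 3 of 15 pairs. A difference in handling or stock between control and exposed fish could raise PVP-AgNP livers too, and they scored 1.43 above controls, which silver in both exposures would also give, so it cannot be told apart from an effect of silver. A response to silver common to both tissues is therefore a hypothesis, found and tested on the same arrays.

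The excess of brain-enriched probes on liver PVP-AgNP 5 rose with the brain level at a slope of 1.009 (log2 on log2), with a median of 5.04% of the brain level, as brain RNA mixed into the sample would give. Its median correlation with brain arrays was 0.739 and with the other liver arrays 0.893, which argues against a swapped label. Carry-over from brain control 1, the 1 brain array on its slide, is a candidate explanation, since its deviations correlated best with that array's own (r = 0.35, next 0.16, across probes). The other 5 livers on the slide correlated with it at -0.14 to 0.08. Both mixed RNA and carry-over remain, and no biological explanation was tested.

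Arrays were also regrouped at random, 100 splits for each comparison with the real one included. For brain AgNO3 1 split called as many as the real 58 (highest other 1), and for liver PVP-AgNP against AgNO3 1 as many as 1019 (highest other 69). It was 1 at 1956 for the tissue difference of AgNO3 (highest other 1725) and 1 at 19818 for liver against brain controls (highest other 14392). In each of these 4 that 1 was the real split, which argues against chance at a share of 1 in 100, not adjusted for the number of comparisons. Of the 1956, however, 1495 were liver AgNO3 calls, a comparison in which another split called more than the real one. For the shared calls 1 split reached 19 (highest other 5). There the real brain calls were kept and only livers regrouped, so splits with few liver calls could share few, and this cannot decide on chance. For brain PVP-AgNP 3 splits called 14 or more, for liver AgNO3 2 called 3166 or more (highest other 6432) and for liver PVP-AgNP 4 called 12 or more (highest other 35). These shares are under 5 in 100, but they are not adjusted for the number of comparisons. In each the highest other split called more than the real one, so these counts alone do not exclude chance. The larger brain PVP-AgNP splits, 54 and 64, largely followed slides 3 and 4. Both also kept control 5 and PVP-AgNP 4 and 5, the 3 arrays with raised negative-control spots, on 1 side. Slide and array quality cannot be told apart there. With slide as a term the real comparison called 8 probes, and with only the 2 groups compared limma called 0 (4056 at an unadjusted p under 0.05). The liver AgNO3 split of 6432 set AgNO3 1 with controls 1, 2, 4 and 6 against AgNO3 2, 3, 4 and 5 with controls 3 and 5, which keeps 4 of the 5 AgNO3 arrays together and puts 4 of the 6 arrays of that part on slide 2, and with slide as a term the real comparison called 1580. Chance cannot be excluded for brain PVP-AgNP against AgNO3, with 8 splits at 1 or more (highest other 14), 1 of them the real one with its groups exchanged. Nor can it be for the tissue difference of PVP-AgNP, with 10 at 6 or more (highest other 4089, many times the real count, for a cause not tested).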

How the results depend on the processing

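Alternatives added after the data were examined were those without the 3 raised-negative-control arrays, with 1 probe name per sequence, each array left out for the differences between tissues, and all for the shared calls, the scores and the tissue-enriched probes. Directions of named probes held in all 560 values, 448 of them on the same side of the threshold, while counts moved, for causes not tested.

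Normexp called 32 probes in brain AgNO3 (58), 6 in brain PVP-AgNP (14), 0 in brain PVP-AgNP against AgNO3 (1; 1710 at an unadjusted p under 0.05 in limma), 39 in liver PVP-AgNP (12), 906 in the tissue difference of AgNO3 (1956) and 12 in the shared calls (19). Quantile normalization called 125 in brain AgNO3, 9 in brain PVP-AgNP, 1257 in the AgNO3 tissue difference and 1 in that of PVP-AgNP (6). It reversed the liver-enriched difference of array medians in AgNO3 livers to 0.043, while the median fitted change of these probes stayed negative (-0.27). Median centring called 7 in brain PVP-AgNP and 0 between the brain exposures (5166 unadjusted), and the series matrix values 129 in brain AgNO3 and 8 in brain PVP-AgNP. The stricter filter gave 24 in brain and 38 in liver PVP-AgNP, and no filter 2 in the PVP-AgNP tissue difference.

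Slide as a term called 23, 8 and 0 (3847 unadjusted) in the brain comparisons in that order, 1580, 19 and 638 in liver, 1172 in the AgNO3 tissue difference and 9 shared calls. Only the 2 groups compared gave 2626, 0 (4056 unadjusted) and 0 (3504) in brain, and 2965, 9 and 826 in liver. Array weights gave 3336, 165 and 2 in brain, 16380, 4381 and 3014 in liver and 1279 shared calls. Without the raised-negative-control arrays, 23 brain probes differed between exposures and 2 in the PVP-AgNP tissue difference, with 0 of its 6 main calls among these 2.

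Deviations of same-numbered arrays correlated at r over 0.1 in 1 of 15 pairs within brain (highest 0.11), 3 of 15 of brain with liver (highest 0.30) and 5 of 13 within liver (highest 0.26), and 2 arrays correlated best with their own number. With the replicate number as a block, limma called 7, 0 (3977 unadjusted) and 0 (4172) in brain, 1505 and 2 in liver against control, 1011 and 0 (3763) in the tissue differences, 0 and 2 alike for both exposures in brain and liver, and 5 shared calls.

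Leaving out 1 array gave 22 to 319 in brain AgNO3, 6 to 189 in brain PVP-AgNP, 0 to 487 between them, 1731 to 4615 in liver AgNO3, 5 to 114 in liver PVP-AgNP, 394 to 1286 between them, 1386 to 2772 and 2 to 358 in the tissue differences and 11 to 31 shared calls. Not run were scan date as a block, since each slide had 1 scan time, and the gene lists. Probes near background limit folds, most on brain control 5.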

Other observations

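The motif counts were chosen after the data were examined. The sequence AGATCGGAAGAG, which begins a common sequencing adapter, lies in 291 probes (0.584%). Of these, 153 were kept in liver and 8 were called for AgNO3 there, and 2 of the 19 shared probes, SINGLET_8133 and SINGLET_9313, carry it.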
